A study of Drosophila melanogaster with 2 samples.

How the data were processed

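The assay was chromatin immunoprecipitation with sequencing (ChIP-seq) of a transgenic Drosophila melanogaster line that carries the protein of gene CG14965 fused at its C terminus to enhanced green fluorescent protein (eGFP). Chromatin came from whole embryos of mixed sex aged 0 to 24 h, was sheared by sonication to 200 to 800 bp and was precipitated with an antibody to GFP, per the labels. The series holds 2 samples in 1 group, which the labels number as biological replicates 3 and 4 and assign to separate biosamples. There is therefore no comparison between conditions. Per the labels' text files, peaks were called with a control library, which was not used here, and no untagged line was analysed here.

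The authors deposited peak lists in narrowPeak form on 2 genome builds, dm6 and dm3. Each replicate has a list of peaks and background regions made for the irreproducible discovery rate procedure (IDR). IDR sets a threshold from how well the ranks of regions repeat between replicates. The series also has such a list for both replicates pooled and a thresholded list called optimal IDR peaks. The optimal dm6 peaks are the 1302 regions of highest signal value in the pooled list, so an optimal peak need not rank high in both replicates. Peak caller, aligner and their versions are not given in the sources used here. Column 7 of the deposited lists is a signal value, a score whose scale is not stated, so it was used only to rank and describe regions within a list. The deposited −log10 significance in column 9 reaches its highest value in 1175 of the 1302 optimal peaks and was used only to break ties. The deposited offset of the summit from the region start gave the summit position. The files give no read numbers, so the depth of each replicate is unknown, and the intervals printed here cover the counting of peaks alone.

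Each test below takes peaks or genes as its units. These are not replicates, so the p-values describe the peak list of these embryos and not the spread between biosamples. The dm6 coordinates were set against the Release 6 genome and the Ensembl BDGP6 gene annotation, whose chromosome names and lengths contain all deposited dm6 regions. No annotation of dm3 was used here, so the dm3 lists served for peak numbers, replicate overlap, rank correlation and the count of regions outside the chromosome arms. Genes annotated as transposable elements were left out of the transcription start sites (TSSs) and counted as a separate feature. Coordinates are on dm6 and start at 1.

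A summit within 500 bp of a TSS was called a promoter peak. Other summits were placed, in this order, in 5′ UTR, coding sequence, 3′ UTR, exon of a noncoding gene, intron or intergenic sequence. The background was the 28405 pooled candidate regions that overlap no optimal peak, since these could have passed the threshold. Shares were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within each family. Intervals of shares are 95% Wilson intervals, those of odds ratios are 95% Woolf intervals, and a share of 0 is given with the limit that 3 counts set. Replicate overlap was the share of the 1302 highest regions of replicate 3 that overlap, by at least 1 bp, one of the 1302 highest regions of replicate 4. It was set against 100 random relocations on the same chromosomes with bedtools shuffle. Rank correlation of the signal was taken across peaks, which are not independent replicates. The difference in median signal was tested by permutation with 100000 resamples, two-sided.

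Gene lists, known motifs and the rule for naming were fixed before the data were examined. A total of 21 lists was tested: cytosolic and mitochondrial ribosomal proteins, respiratory chain, proteasome, translation factors, histones, transfer RNAs, small nuclear and nucleolar RNAs, Hox, segmentation, dorsoventral, Notch and Enhancer of split, neural, muscle, germline and piRNA, blood with fat body and gut, insulator proteins, Polycomb and trithorax group, dosage compensation, cell cycle and heat shock genes. In the annotation used here 12 listed symbols had no match and were left out. Noncoding members of protein-coding lists were left out too. Of 9 dosage compensation genes found, 7 were tested, without the noncoding lncRNA:roX1 and lncRNA:roX2. Genes with a peak within 500 bp of any TSS were counted against all other genes on the chromosome arms, or against protein-coding genes for protein-coding lists. The rule named the 25 peaks of highest signal by the nearest TSS, up to 4 members per list with the strongest promoter peaks, and CG14965 at its own locus.

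Sequence within 50 bp of each summit was searched on both strands for 14 known motifs. The background was 13020 candidate regions outside the peaks, 10 per peak, with the same share of promoters. Words of 8 bases were ranked on arms 2L and 2R by Fisher's exact test, one-sided, and the 10 best were tested on 3L, 3R and X. Divergent promoters were TSSs with a TSS of another gene on the opposite strand, transcribed away from it, within 1000 bp.

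Motif, word and list tests were first tested on simulated data. The CTCF element was planted, in its form AGATGGCGC, in 5% of 1302 shuffled sequences. It was called in 20 of 20 runs, and words from it were called in 20 of 20. Other motifs were called 23 times over these runs. Of these calls 19 were of Pho, whose search pattern has a match on the opposite strand of the planted element. With nothing planted, 1 motif and 1 word were called over the 20 runs. Simulated peaks and background were drawn from the same pooled candidate regions. They did not differ in GC content as the real ones did (38.3% against 45.7%). These runs therefore give no rate of false calls from base composition. Lists were simulated on the 17 with at least 10 protein-coding members. A gene list with 35% of its members bound, against 5% of 13968 genes, was called in 20 of 20 runs, with 2 calls of other lists, and no list was called with nothing planted.

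Alternatives covered the build, the promoter window, the background, the overlap rule, the word length, the 651 strongest peaks in place of all 1302, and the 1302 highest regions of each replicate alone. A background matched on GC content, and counts of divergent promoters by the nearest TSS of each peak, against candidate regions, or with both changes, were added after seeing the data. Software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and bedtools 2.31.1.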

Results

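Binding of CG14965-eGFP was profiled by anti-GFP ChIP-seq in whole Drosophila embryos aged 0 to 24 h, in 2 biological replicates numbered 3 and 4. The pooled data gave 1302 optimal IDR peaks on dm6, which covered 532771 bp or 0.387% of the chromosome arms. Some entries overlap: merged, the peaks form 1269 regions and the 30000 pooled candidate regions form 26682. The tests below counted each entry as a separate unit. Peaks had a median width of 436 bp (range 109 to 836 bp). No read numbers accompany the lists, so the depth behind each replicate is unknown.

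The deposited signal value, a score with no stated scale, ran from 69.8 to 8276 with a median of 101, and 36 peaks exceeded 1000. The strongest peak lay on 3R at 16798435 to 16799270, in intergenic sequence of the Bithorax complex between the Hox genes Ubx and abd-A. Its signal was 5133 in replicate 3 and 3188 in replicate 4, and the nearest TSS, of the noncoding gene lncRNA:CR45750, was 1726 bp away. The next strongest peak, on 2R at 20884174 to 20884956 with a signal of 7893, lay in coding sequence of otp, a homeobox gene. The third, with a signal of 3903, lay on chromosome 4 at 424458 to 425100 near lncRNA:CR43437.

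Among the 25 strongest peaks, 8 were promoter peaks, 7 lay in introns, 9 in intergenic sequence and 1 in coding sequence. The promoter peaks belonged to nxf4 (3490), CG6345 (3232), CG10947 (2994), CG43066 (2759), Serinc (2310), CG3556 (2304), LSm7 (1836) and Obp99b (1767), with the pooled signal value in parentheses. LSm7 encodes a subunit of an RNA-processing ring complex, and Obp99b an odorant-binding protein. A pair of the intronic peaks lay in Eip75B, a nuclear receptor gene induced by ecdysone, on 3L at 17988015 to 17988666 (3581) and 18019601 to 18020124 (2164). Other intronic peaks lay in SNF4Agamma (3229), sick (2914), Spn (2401), pnt (2192) and CG32264 (2148). Intergenic peaks had as their nearest genes unc-5 (3458), a netrin receptor gene, Indy (3099), CG6040 (2951), CG34260 (2434), CG44439 (2225), CG6465 (2123) and bor (2100), besides both noncoding genes above. In all, 13 of the 25 summits lay more than 2000 bp from any TSS.

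The replicates ranked the strongest sites alike. All 25 strongest peaks were among the 25 highest regions of replicate 3 and among the 25 highest of replicate 4. Of the 1302 highest regions of replicate 3, 855 (65.7%, 95% Wilson interval 63.1 to 68.2%) overlapped one of the 1302 highest of replicate 4. Random relocation gave a mean of 0.800% and a highest value of 1.54% over 100 draws. The share was 76.6% among the 500 highest regions and 43.2% among the 5000 highest. Of the 1302 optimal peaks, 1096 (84.2%) overlapped one of the 1302 highest regions of replicate 3. For replicate 4 the number was 991 (76.1%), and 1293 overlapped any of its regions. Spearman's rho of the signal was 0.635 (0.600 to 0.667) across the 1293 peaks with a region in both replicates, and Pearson's r on log2 signal was 0.869. Both are correlations across peaks, which are not independent replicates. The peaks were picked by the signal of both replicates pooled, so these values and the agreement of the 25 strongest are not independent of that choice.

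**Figure D1:**
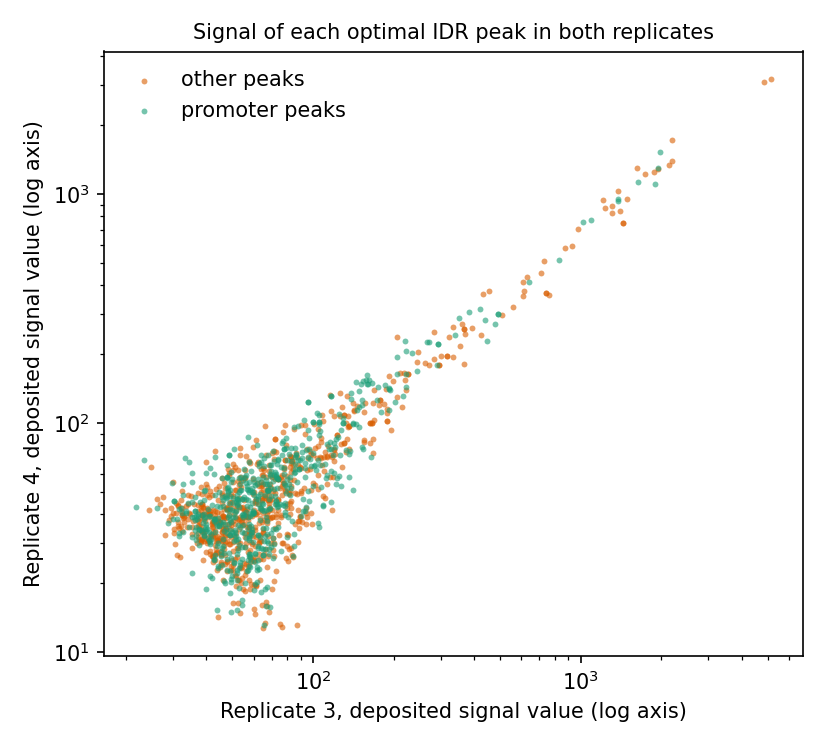
Deposited signal value of each of the 1293 optimal peaks present in both lists, replicate 3 on the horizontal and replicate 4 on the vertical axis (both log axes, no stated unit), with promoter peaks in green and other peaks in orange. The strongest sites lie along a narrow diagonal, and the scatter widens at low signal; Spearman's rho was 0.635.

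Peaks were enriched at promoters and sparse in coding sequence. Of the 1302 summits, 587 (45.1%, 42.4 to 47.8%) lay within 500 bp of a TSS, against 23.5% of 28405 candidate regions outside the peaks (odds ratio 2.67, 2.39 to 2.99, Fisher's exact p = 9.43e-62). Coding sequence held 17 peaks (1.31%, 0.817 to 2.08%) against 20.4% of candidate regions (odds ratio 0.0518, adjusted exact p = 3.06e-97). The 3′ UTRs held 13 peaks against 3.04% of candidate regions (odds ratio 0.322, adjusted exact p = 4.9e-06). Introns held 470 peaks (36.1% against 34.5%) and intergenic sequence 195 (15.0% against 16.6%), and neither share passed the test (adjusted exact p = 0.259 and 0.165). The 5′ UTRs (8 peaks, adjusted exact p = 0.165) and noncoding exons (12 peaks, adjusted p = 0.879) did not pass it either. No summit lay in an annotated transposon, which allows a share of up to 0.23%, whereas 174 candidate regions did (Fisher's exact p = 0.000642). Median signal was 103 at promoter peaks against 99.1 at others, a difference of 4.09 that did not pass (permutation p = 0.11). It passed with the signal of replicate 4 alone (3.88, permutation p = 0.0106) and the 1000 bp window (5.93, permutation p = 0.037), and was 0.540 with replicate 3 alone. The 99th percentile went the other way, 1901 at promoter peaks against 2945 at others, untested.

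**Figure D2:**
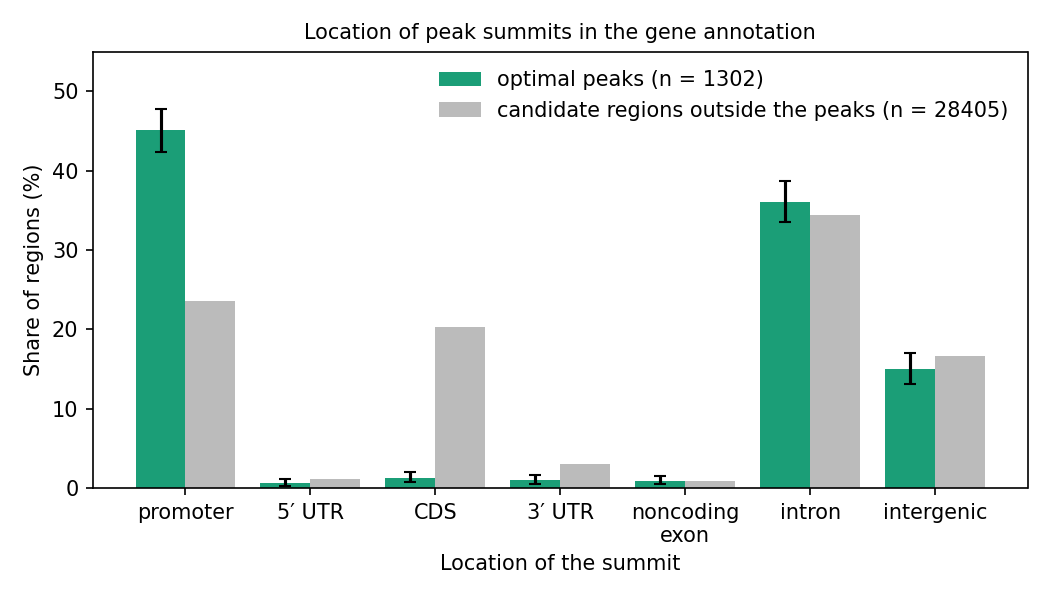
Share of summits in each annotated location, in percent, for the 1302 optimal peaks (green, with 95% Wilson intervals) and the 28405 candidate regions outside the peaks (grey). Promoters hold 45.1% of peaks against 23.5% of candidate regions, and coding sequence holds 1.31% against 20.4%.

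Across chromosomes, the X held 232 peaks (17.8%, 15.8 to 19.99%) against 14.6% of candidate regions (odds ratio 1.27, Fisher's exact adjusted p = 0.0093 over 6 chromosomes). Arms 2L, 2R, 3L and 3R held 241, 236, 290 and 296 peaks and chromosome 4 held 7, none different from candidate regions (adjusted p from 0.294 to 0.919). The X call was lost against chromosome length (odds ratio 1.02, binomial exact test, adjusted p = 0.827). With the 1302 highest regions of 1 replicate the odds ratio was close to the 1.27 of the pooled list and the test did not pass (1.21, adjusted exact p = 0.105 for replicate 4 alone; 1.20, adjusted p = 0.0761 for replicate 3 alone).

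Genes of the cytosolic ribosome were bound at their promoters far more often than other genes. A peak lay within 500 bp of a TSS in 35 of 92 cytosolic ribosomal protein genes (38.0%), against 4.68% of other protein-coding genes (odds ratio 12.5, 8.16 to 19.2, Fisher's exact adjusted p = 2.68e-21 over 21 lists). Among genes with any candidate region at a TSS the odds ratio was 6.69 (4.24 to 10.6; 45.5% against 11.1%). The strongest members were RpL7 (signal 318; 166 in replicate 3 and 150 in replicate 4), RpS27 (291; 180 and 112), RpL23A (234; 130 and 106) and RpL30 (207; 120 and 82.1). In all, 684 of 13968 protein-coding genes had a promoter peak. Translation factor genes had a peak in 8 of 54 (14.8%, odds ratio 3.41, adjusted exact p = 0.0471), led by eIF2beta (1342; 827 and 517), which encodes a subunit of the initiator tRNA carrier. The other leading members were eIF6 (238), eEF1gamma (162) and eIF1 (145). The summit counted for eIF1 lay 310 bp from its TSS and 71 bp from that of the ribosomal protein gene RpL28. Odds ratios of translation factors ran from 2.745 to 4.04 in the alternatives, and only the 1000 bp window passed (3.12, adjusted exact p = 0.0337).

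Genes of other cell functions did not pass the test. Mitochondrial ribosomal protein genes had a peak in 5 of 73 (adjusted exact p = 0.951), with mRpL41 (498), mRpS10 (438), mRpS23 (371) and mRpL23 (155) the strongest. The respiratory chain had 3 of 87, blw (95.9), ND-ASHI (93.4) and ND-MWFE (81.9), and the proteasome had 1 of 48, Rpn5 (102). Heat shock genes had 2 of 22, the chaperone genes Hsp83 (374) and Hsp27 (116). Insulator and architectural protein genes had 2 of 21, Chro (456) and Trl (143), the latter also the only bound gene among 25 of the Polycomb and trithorax groups. Cell cycle and replication genes had 3 of 31, dpa (101), dup (73.2) and Dp (70.9), and histone genes had 1 of 115, His2Av (85.8). Only 3 of these histone genes had any candidate region. Adjusted p values of these lists ran from 0.244 to 1. With the highest regions of replicate 3 alone, 5 of the 25 Polycomb and trithorax group genes had a peak (odds ratio 4.64 against 0.809 in the pooled list, adjusted exact p = 0.0558). Heat shock genes had 3 of 22 with replicate 4 alone (odds ratio 3.46 against 1.945, adjusted exact p = 0.292) and 2 of 22 with replicate 3 alone. Histone genes had 0 of 115 with replicate 4 alone, which allows a share of up to 2.61%.

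Developmental genes were rarely bound at their promoters, at rates that these list sizes cannot separate from other genes. The bound members were bcd (70.8) among 23 segmentation genes, elav (128) among 24 neural genes, sls (92.3) among 19 muscle genes and fkh (179) among 18 blood, fat body and gut genes. No member had a promoter peak among 8 Hox genes, 19 dorsoventral genes, 18 Notch and Enhancer of split genes, 19 germline and piRNA genes and 7 dosage compensation genes. These counts of 0 allow shares of up to 37.5%, 15.8%, 16.7%, 15.8% and 42.9%, and each adjusted p, those of the lists with bound members above included, was 1. With either replicate alone, such counts moved by at most 1 gene. Transfer RNA genes had a peak in 5 of 295 (1.69% against 4.20%, adjusted exact p = 0.189), with tRNA:Tyr-GTA-1-8 the strongest (167). Small nuclear and nucleolar RNA genes had 9 of 306 (adjusted exact p = 0.951), led by snoRNA:Or-CD11a (145), whose peak was also that of eIF1.

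Whether bound promoters are more often divergent depended on how they were counted. Of 953 TSSs with a peak within 500 bp, 480 (50.4%) had a divergent TSS of another gene within 1000 bp, against 31.0% of 23158 TSSs without a peak. The odds ratio was 2.26 (1.99 to 2.57, Fisher's exact p = 4.98e-34), across TSSs, where a peak counts for every TSS within 500 bp. The counts that follow were chosen after seeing the data. With each peak counted for its nearest TSS alone, 197 of 575 TSSs (34.3%) were divergent against 31.7% of all others, which include TSSs near a peak that is nearer another (odds ratio 1.12, 0.944 to 1.34, Fisher's exact p = 0.204). Against TSSs with a candidate region and no peak, the odds ratio was 1.46 (1.28 to 1.67, Fisher's exact p = 3.23e-08). With both changes, by peak, 198 of 587 (33.7%) were divergent against 31.6% of 6682 promoter candidate regions (odds ratio 1.10, 0.920 to 1.32, Fisher's exact p = 0.309).

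At its own locus, CG14965 (FBgn0035414, 3L 3190622 to 3192491, minus strand) had no summit of an optimal peak in its gene body or within 500 bp of its TSS. The nearest lay at 3192985 to 3193223 with a signal of 374 (222 in replicate 3 and 144 in replicate 4) and ranked 84. It was the promoter peak of the neighbouring Hsp83, 113 bp from that gene's TSS. Within the gene body the pooled list held a region at 3190998 to 3191433 with a signal of 23.8, ranked 19252 of 30000, and another crossed its end at 3190343 to 3190778 (ranked 28324). Replicate 4 had a region at 3190916 to 3191339 with a signal of 41.3, ranked 732. Replicate 3 had none at that place but regions across both ends of the gene body, at 3190210 to 3190669 (signal 13.3, ranked 18171) and 3192126 to 3192585 (16.3, ranked 11555).

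The DNA element bound by CTCF, an insulator protein, was the most enriched of 14 known motifs. The sequence AGRKGGCGC lay within 50 bp of 77 summits (5.91%), against 0.453% of 13020 location-matched candidate regions (odds ratio 13.8, 9.79 to 19.5, Fisher's exact adjusted p = 1.08e-43). It was present at 3.24% of promoter peaks (odds ratio 7.18) and 8.11% of other peaks (odds ratio 18.0), and at 10 of the 25 strongest peaks. Smaller enrichments passed for core promoter motif 6 (1.61% against 0.722%, adjusted exact p = 0.0119), the TATA box (5.07% against 3.43%, adjusted p = 0.0173), the E-box CACGTG (2.23% against 1.31%, adjusted p = 0.0348) and the element of the insulator protein Su(Hw) (1.08% against 0.492%, adjusted p = 0.0353). The E-box CAGCTG was less frequent in peaks (4.61% against 6.38%, adjusted exact p = 0.0348). Elements of DRE (adjusted exact p = 0.236), BEAF (0.504), GAGA (0.313), Zelda (0.598), Pho (0.6), the initiator (0.615), motif 1 (0.615) and motif 7 (0.364) did not pass. Sequence at summits had a mean GC content of 38.3% against 45.7% in the matched regions. With either replicate alone, the CACGTG call was lost (odds ratio 1.18 and 1.32, adjusted exact p = 0.532 and 0.372), and DRE passed (odds ratio 2.115 and 2.49 against 1.55 in the pooled list, adjusted exact p = 0.0364 and 0.000315), for replicate 4 and replicate 3. With a background matched on GC content, chosen after seeing the data, the odds ratio of CACGTG was 2.66 (adjusted exact p = 0.000591). The calls for motif 6 (odds ratio 1.46 against 2.25, adjusted exact p = 0.352), the TATA box (0.964 against 1.502, 0.902), CAGCTG (1.20 against 0.7095, 0.374) and Su(Hw) (2.001, 1.07 to 3.73, against 2.20, 0.118) were lost.

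**Figure D3:**
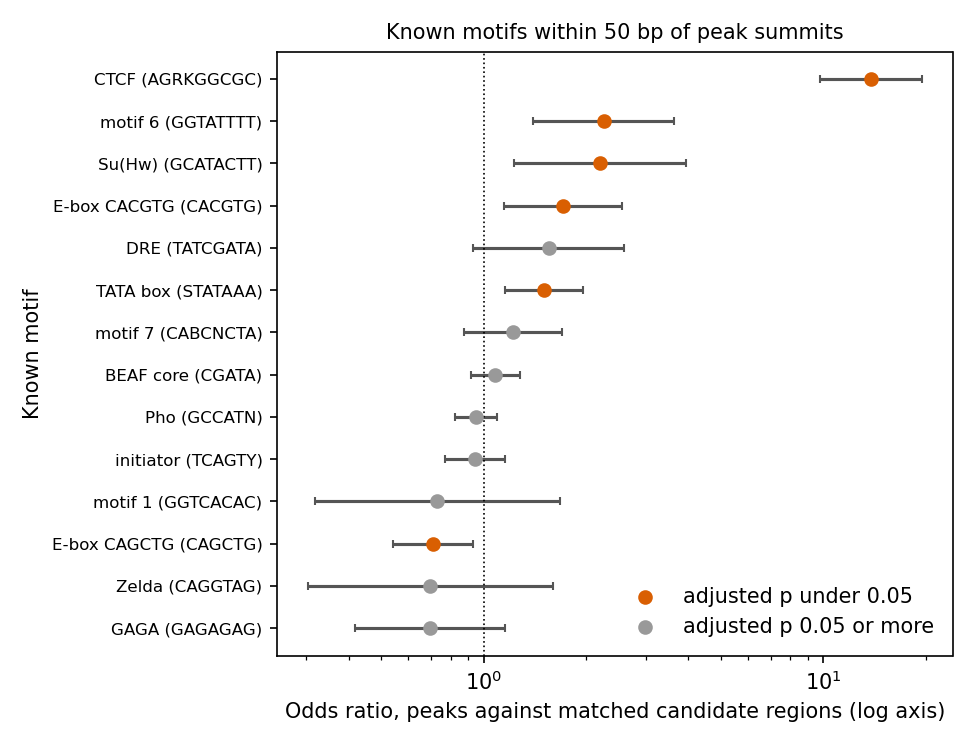
Odds ratio of each of the 14 known motifs within 50 bp of the summit, 1302 peaks against 13020 matched candidate regions, on a log axis with 95% intervals as bars. Orange points pass an adjusted p of 0.05; the CTCF element stands apart at 13.8.

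A search for words of 8 bases that used no prior motif returned the same core. Ranked on arms 2L and 2R, the best word of 8 bases was AGATGGCG, and on 3L, 3R and X it lay near 39 of 818 summits (4.77%) against 0.327% of candidate regions (odds ratio 15.2, Fisher's exact adjusted p = 2.74e-23). The overlapping word GATGGCGC was near 33 summits (4.03%, odds ratio 10.1, adjusted exact p = 9.98e-17), and AGAGGGCG near 11 (1.34%, odds ratio 4.32, adjusted p = 0.000739). The odds ratios of AGATGGCG and GATGGCGC were 8.765 and 6.625 with replicate 3 alone, and 12.1 and 10.5 with replicate 4 alone. Of the 10 best words 9 passed on the test arms. The others were rich in A and T, with ATTTTTAA the most frequent (4.52% against 1.84%, odds ratio 2.53, adjusted exact p = 1.48e-05). At 6 bases the search did not return the core: all 10 best words were rich in A and T, and all passed, with AAATAA the most frequent (26.4% against 16.9%, odds ratio 1.77, adjusted exact p = 1.58e-10). The word search was not repeated with a background matched on GC content, which was 38.3% at summits against 45.7% in the matched regions. Words rich in A and T may therefore pass through base composition alone.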

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

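The dm3 lists hold candidate regions on heterochromatic and unplaced sequences, whose location no comparison above uses; with no control library analysed here, any count above the limit that a count of 0 allows (3 regions) was taken up. Replicate 4 had 354 such regions among 29807, replicate 3 had 34 among 30000, and the pooled list had 85 among 25017. None was in the dm3 optimal list of 1285 peaks. The difference between the replicates was not tested against any explanation. All regions of the dm6 lists analysed here lie on sequences named as chromosome arms. Whether these dm6 arms include heterochromatic sequence that dm3 names separately was not examined, so dm6 regions may lie in it.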

How the results depend on the processing

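The GC-matched background and the counts of divergent promoters by nearest TSS or against candidate regions were chosen after seeing the data; all other alternatives were set before. No paired analysis was possible because the series has only 1 group. The promoter share stayed above its background in every alternative run (32.6 to 56.6%; 41.9 to 48.3% with 1 replicate), as did replicate overlap (43.2 to 76.6%). The odds ratio of divergent promoters ran from 1.87 to 2.83 in the alternatives set before. It was 1.12 (Fisher's exact p = 0.204) with each peak counted for its nearest TSS alone, 1.46 against TSSs with a candidate region and no peak, and 1.10 (Fisher's exact p = 0.309) with promoter peaks by nearest TSS against promoter candidate regions. The rank correlation was 0.705 over the 651 strongest peaks. Chromosome calls fell to 0 against chromosome length and were 0 with either replicate alone. Gene list calls were 1, the cytosolic ribosomal proteins, with the 250 bp window, candidate-region genes as background, the nearest TSS, the 651 strongest peaks and either replicate alone. Small nuclear and nucleolar RNA genes turned to enrichment with the 1000 bp window (9.80%, adjusted exact p = 0.0202). In that count 1 peak can stand for several members, which the test takes as independent. The peak on 2R at 9095000 to 9095435 counts for both snoRNA:Psi28S-2949 and snoRNA:Or-aca5. With the nearest TSS of each peak alone, 2 of 306 genes had a peak (odds ratio 0.205, adjusted exact p = 0.0685). Enriched motifs numbered 5 as reported, 3 at promoter peaks, 1 at other peaks, 2 in the 651 strongest, 3 with GC matching (2 of the 5, with Pho new) and 5 to 6 with 1 replicate (4 of the 5 in each, without CACGTG and with DRE new). CACGTG was also lost within 100 bp, with flanking windows, at other peaks and in the 651 strongest, and DRE also passed with flanking windows (odds ratio 4.91, adjusted exact p = 0.00169). Motif 7 passed with flanking windows (adjusted exact p = 0.0383) and in replicate 4 alone (0.0497). The odds ratio of Su(Hw) was 5.87 in the 651 strongest peaks (adjusted exact p = 0.000246) and 4.71 with flanking windows (0.00401). Besides GC matching, Su(Hw) did not pass at promoter peaks (2.60, adjusted exact p = 0.139) or at other peaks (2.395, 0.0816). Directions turned for GAGA within 100 bp (5.30% of peaks, adjusted exact p = 0.00765), CAGCTG (4.61%) with flanking windows or GC matching, and TATA (5.07%) and Pho (19.4%, odds ratio 1.24, adjusted exact p = 0.0343) with GC matching. The CTCF element in its form AGATGGCGC holds a match to the Pho pattern, and its other forms hold none. Planting this form alone brought a Pho call in 19 of 20 simulated runs. Pho was not tested at peaks without the element, so the Pho call with GC matching cannot be taken as separate evidence. Pho within 100 bp (odds ratio 0.851, adjusted exact p = 0.0182) and GAGA with flanking windows (0.398, adjusted exact p = 0.00175) were depleted. Of motifs, the largest turn that did not pass was motif 1, from an odds ratio of 0.7305 to 2.06 in replicate 4 alone (2.005 with flanking windows), and GAGA also went from 0.695 to 1.20 in replicate 4 alone. Passing words numbered 3 at 10 bases, 5 with flanking windows, 4 in the 651 strongest and 5 to 7 with 1 replicate. The signal difference of promoter peaks passed with the 1000 bp window (5.93, permutation p = 0.037) and ranged from 0.540 to 3.88 with 1 replicate, where it passed in replicate 4 alone (p = 0.0106). The causes of these changes were not tested. Depth is unknown, so how many weaker sites were missed cannot be given.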

Other observations

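The tests of the backwards element and of GC content for ribosomal protein promoters and for location were written before their results were seen; the other tests here, and the rank groups, were chosen after. Both Hox complexes held strong sites away from promoters. The Antennapedia complex (3R 6661427 to 6999228) held 7 peaks, among them 1131 in an intron of Antp at 6973186 to 6973645, 799 near Scr at 6854311 to 6854759 and 650 near ftz at 6870775 to 6871153. The Bithorax complex (3R 16656623 to 16972236) held 4, including the strongest peak of all. A hypothesis that these complexes hold more peaks than candidate regions give was left open: 0.845% of peaks and 0.556% of candidate regions lay there (odds ratio 1.52, 0.825 to 2.81, Fisher's exact p = 0.183). Of the 50 strongest peaks 4 did (Fisher's exact p = 0.00019), a group size picked after these peaks had been seen.

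Within 100 bp of the summit, the word search also returned words of another sequence. TACACTGA lay near 30 of 818 summits on the test arms (3.67%) against 0.818% of candidate regions (odds ratio 4.62, Fisher's exact adjusted p = 3.2e-09). The overlapping ACACTGAG was near 18 (2.20%, odds ratio 2.50, adjusted exact p = 0.00208) and CACTGAGA near 25 (3.06%, odds ratio 2.58, adjusted p = 0.000215). Within 50 bp in replicate 4 alone, where the search returned both again, ACACTGAG was not enriched on the test arms (0.369% against 0.428%, odds ratio 0.860, adjusted exact p = 0.682) and CACTGAGA did not pass (odds ratio 2.04, adjusted exact p = 0.0838). No explanation was tested.

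The CTCF element was concentrated at the top of the list. It lay within 50 bp of 24 of the 50 strongest summits (48%, 34.8 to 61.5%), 15 of the next 150 (10%, 6.15 to 15.8%) and 38 of the remaining 1102 (3.45%, 2.52 to 4.70%). The longer CTCF-type consensus CCASYAGRKGGCRS, at up to 2 mismatches within 100 bp, was found at 68% of the 50 strongest, 12.7% and 6.90% of the later groups and 4.68% of matched candidate regions. To test the hypothesis that the strongest peaks hold a longer CTCF-type consensus and not its core alone, 100 versions kept the core AGRKGGC and had the other columns shuffled. Of these, 2 were found in at least as many of the 50 strongest peaks (median 20%, highest 70%), so the bases beside the core may contribute. The shuffled columns include those that match the last bases of the element AGRKGGCGC. The test therefore cannot show whether bases beyond that element contribute.

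Of technical explanations for the CTCF element, GC content differs in the opposite direction over all peaks. Summits averaged 38.3% GC against 45.7% in the location-matched regions, and the element is rich in G and C. Matching on GC content was therefore likely to raise the odds ratio. The value of 25.4 (14.8 to 43.7) over a GC-matched background is thus a weak test of this explanation. The 25 strongest peaks averaged 47.4% GC. Base composition in any order is argued against by the element read backwards, which was at 0 of 1302 peaks (odds ratio 0.285, 0.0171 to 4.75, below the 9.79 at which the element's interval starts). A mislabelled sample, from a line with a tag on another protein, stays open: 2 pooled candidate regions overlapped the CG14965 gene body, 1 of them across its end, and 19.7% of 2409 genes of similar length had at least as many, so the tagged locus identifies no line. With 1 group, no biological explanation was tested. That the tagged protein may reach these sites itself or beside a CTCF-type protein is a hypothesis only.

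None of the 36 peaks at ribosomal protein promoters carried the CTCF element, which allows a share of up to 8.33% and so does not set them apart from the 3.24% of all promoter peaks. Signal at all housekeeping promoters alike is argued against, since the mitochondrial ribosome, respiratory chain, proteasome and translation factor lists together had a promoter peak in 17 of 262 genes (6.49%, 4.09 to 10.1%), below the interval of cytosolic ribosomal proteins (28.8 to 48.2%). GC content of the promoters is argued against by an odds ratio of 12.8 (8.32 to 19.7) stratified by GC. Signal that follows transcription could remain, as neither expression nor an untagged line was analysed here. No biological explanation was tested.

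The low mean GC content of peaks is a candidate explanation for their location, as coding sequence is richer in G and C. The 25 strongest peaks do not share it, at 47.4% against 38.3% over all peaks. Against 6510 candidate regions matched on GC content, promoters kept an odds ratio of 2.60 (2.30 to 2.94) and coding sequence one of 0.143 (0.0880 to 0.233), where the unmatched values were 2.67 and 0.0518. GC content as the whole cause is thus argued against for both, and part of the coding-sequence difference went with it. How the caller set its candidate regions was not tested, and no biological explanation was tested.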
